A study of Mus musculus with 6 samples.

How the data were processed

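The deposited data were 3 matrices of raw UMI counts, 1 per group, which per the file headers came from cellranger-6.0.2. Each held 32285 genes and 142 antibody features: 4 hashtags and 138 panel antibodies, 3 of them isotype controls. The submitters' processing notes name bcl2fastq, Cell Ranger and the GRCm39 (mm39) mouse genome. Per the labels, left quadriceps were digested with collagenase II and dispase II, red blood cells were lysed, and each animal was tagged with a TotalSeq-C hashtag. The 4 animals of a group were then pooled, stained with the TotalSeq-C mouse universal cocktail and loaded on 1 lane of the 10x 5' v2 assay. All 3 libraries were used. Gene symbols repeated in the matrices (78) were kept as separate genes.

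Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Median mitochondrial shares were 0.186%, 0.195% and 0.377% in uninjured, subcritical and critical cells, so that limit removed almost nothing. Scrublet (as in scanpy, with its default expected rate) marked 0, 22 and 3 doublets, 0.297% of 8427 barcodes, which means that it has not worked here. Cells with several hashtags (60, 109 and 127) were removed. As an alternative, the cells with the highest doublet scores were left out, at a rate of 0.8% per 1000 cells. In all, 7942 cells remained, of which 947, 1188 and 1149 (44.4%, 42.8% and 37.9%) were assigned to 1 animal. Hashtags were called with a bounded negative binomial mixture per hashtag. The lowest count that gave a call ran from 2 to 7 over the hashtags of the 3 libraries, so some calls rest on few counts. The form of the mixture was settled after the hashtag counts were seen and before any gene was compared.

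Counts were scaled to the cell total and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8 (random seed 1) gave the clusters, with all libraries together and no batch correction. A cluster took the class whose markers had the highest mean log2 fold over the other clusters, if at least 3 of them were found in at least 10% of its cells. It took no name where its top 10 genes held at least 1 marker of another class and at least as many of other classes as of its own, or where a shallow or narrow lead came with no own marker among them, a clause set after the clusters were seen. That clause kept out cluster 1 (4.09%, 5.19% and 4.87% of critical, subcritical and uninjured cells) and cluster 18, of dividing cells. An unnamed cluster was counted in with FAP-like cells, as an alternative, if its nearest class was FAP or tenocyte, so cluster 18 need not be of FAPs. Classes are called FAP-like, macrophage-like and so on because they rest on transcripts alone. Cluster 9, of low depth, is part of the FAP-like class (156, 127 and 9 cells).

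Where animals could be told apart, counts were summed per animal and class, with at least 20 cells per animal, and tested with edgeR (TMM, filterByExpr, robust quasi-likelihood fit over all animals, Benjamini-Hochberg adjusted p under 0.05). DESeq2 served as an alternative. Group means are CPM with SD over animals, and SE is that of the fitted log2 fold change. Macrophage-like animals had 83 to 276 cells and 128651 to 510810 UMIs, and endothelial-like animals 29 to 353 cells and 45184 to 653646 UMIs. Critical replicate 1 and subcritical replicate 3 had too few endothelial-like cells. Lists were tested with camera (preset correlation 0.01, and again with an estimated one) and fry. Shares between animals were compared with exact two-sided permutation tests.

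Where animals could not be told apart, UMIs were summed over a library's cells of the class and given as CPM. Log2 folds use a pseudocount of 1 CPM, with exact binomial intervals on the counts of both libraries at 95% confidence, covering counting error only. Levels have exact Poisson and shares exact Clopper-Pearson intervals, and a share of 0 is given with the limit of 3 counts in place of an interval. A fold against a library with no count is given against 3 counts over that library as at least that many-fold. List members needed a mean of 5 CPM, and each median was placed among 10000 random lists of the same size matched on mean level (100 neighbours per gene). These positive counts and percentiles describe these libraries only. Proliferating cells were counted after thinning to 1074 UMIs, the 20th percentile over FAP-like cells, with smaller cells left out. Antibody aggregates were cells with at least 1000 antibody counts, over 50% of them from 1 antibody (10, 19 and 23 cells).

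Tests, lists, markers and alternatives were set before the data were examined, except where the text says otherwise. The 28 lists were fibrillar collagen and crosslinking, matricellular and activated fibroblast, basement membrane, TGF-beta pathway, matrix proteases and inhibitors, adipogenic, universal progenitor fibroblast, parenchymal fibroblast, chemokines and cytokines, complement, growth factors and antagonists, tenogenic and chondrogenic, proliferation, interferon response, dissociation and stress, hypoxia and glycolysis, Wnt pathway, pro-inflammatory macrophage, alternatively activated and resident macrophage, scar-associated and lipid-handling macrophage, antigen presentation, lysosome and phagocytosis, endothelial activation and angiogenesis, myogenic, muscle fibre, and immune, fibroblast and red blood cell transcripts. They share members: Spp1, for example, is in a fibroblast and a macrophage list.

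Named genes followed a rule. With a test, they were up to 6 genes per direction with the largest log2 fold change among those past the threshold with a mean of at least 20 CPM and no overlap between the 2 groups' animals, leaving out predicted, ribosomal, mitochondrial and sex-check genes. Added to them were, per list with a member past the threshold or a camera call, the 2 to 4 such members that changed most, and from other lists the member with the smallest p. Without replicates, they were up to 10 genes per direction with the largest log2 fold among genes with at least 50 CPM in the higher library and an interval excluding 2-fold, plus the 2 to 4 members of each list that differed most. The text names part of what the rule gives. Rps28, Rps29, Nrgn and Gp9 were chosen after their values were seen, to describe ribosomal genes and genes that platelets express.

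Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The methods were tested on simulated data of the same size. With 100 changed genes of each size, edgeR recovered 69% at log2 1 and 91% at log2 2 for macrophage-like cells, with 4.76% false calls, and 49% and 96% for endothelial-like cells between the wounds, with 5.23% false calls. The fold intervals covered the true value for 94% to 99% of genes. Those counts were drawn with counting error only, which the intervals assume, so this coverage cannot speak to spread between cells or animals. Of lists simulated with no common change, 88.9% to 96.3% fell within the middle 95% of random lists.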

Results

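Single-cell gene expression and cell-surface protein were measured together in the quadriceps of male wild-type mice, 7 days after injury. A critical volumetric muscle loss injury removes more muscle than can grow back, and the gap fills with scar and fat, while a subcritical injury of the same kind is repaired. The 3 groups were uninjured, subcritical and critical, with 4 animals in each. The cells of each animal carried a hashtag antibody, the 4 animals of a group were pooled, stained with a panel of barcoded antibodies and run as 1 library, so group, pool, staining tube and library cannot be told apart. The files held 2195 barcodes for the uninjured, 3071 for the subcritical and 3161 for the critical library, with 5681346, 4954129 and 7138662 transcript counts (UMIs) and medians of 1816, 1206 and 1608 UMIs per barcode. Antibody counts came to 523489, 492171 and 462692. After filtering, 2134, 2777 and 3031 cells remained.

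The question the series title puts is about fibro-adipogenic progenitors (FAPs), the muscle fibroblasts that lay down matrix and can turn into fat cells. Only 6.28% of FAP-like cells of the critical, 4.81% of the subcritical and 6.63% of the uninjured library could be traced to 1 animal by hashtag, against 90.2%, 92.8% and 73.5% of macrophage-like cells. FAP-like cells are therefore compared as 1 library per group: their values have no replicates, no test was made, and each interval is a 95% interval covering counting error only. Macrophage-like and endothelial-like cells, and 1 further cluster, were tested between animals. Of endothelial-like cells only 31.9% of the critical, 32.7% of the subcritical and 52.3% of the uninjured library were tagged. Their tests describe that part of the class.

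Injured muscle held many macrophages and fibroblasts where uninjured muscle held mostly endothelium, and the libraries of the injured groups had similar make-up. Macrophage-like cells were 1.59% (95% exact interval 1.11 to 2.22) of the uninjured library, 29.9% (28.2 to 31.6) of the subcritical and 26.2% (24.6 to 27.8) of the critical. FAP-like cells were 7.78% (6.68 to 9.0), 27.0% (25.3 to 28.7) and 29.9% (28.3 to 31.6), but 14.4% of the subcritical and 13.5% of the critical library with coarser clusters. Endothelial-like cells took 61.0% (58.9 to 63.0) of the uninjured library and 21.7% and 21.0% of the subcritical and critical libraries, and mural-like cells, the pericytes and smooth muscle of vessel walls, 11.5%, 5.65% and 7.13%. Myogenic-like cells, which hold the satellite cells that rebuild fibres, were 1.08%, 3.46% and 3.73%. Of the non-immune cells alone, FAP-like cells were 8.85%, 42.1% and 43.0%.

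Between animals, tagged cells gave the same directions against uninjured muscle, although no class passed correction over the 24 tests. With 4 animals against 4 the exact two-sided permutation p cannot fall under 0.0286, and its adjusted value was 0.0857. Tag rates differed by class and group, at 31.9%, 32.7% and 52.3% of critical, subcritical and uninjured endothelial-like cells. Shares of tagged cells therefore reflect hashtag uptake as well as make-up. Macrophage-like cells were 4.41% ± 2.90 (SD, n = 4) of tagged cells in uninjured, 65.4% ± 7.23 in subcritical and 62.2% ± 2.59 in critical animals. Endothelial-like cells were 76.3% ± 12.3, 15.4% ± 6.67 and 16.0% ± 5.69. For both, each injured group stood apart from the uninjured animals with that smallest exact p. Between critical and subcritical animals the exact p was 0.6 (adjusted 0.758) for macrophage-like and 0.914 (adjusted 0.984) for endothelial-like cells. Tagged FAP-like cells were 0.914% ± 0.636, 2.91% ± 0.887 and 5.30% ± 1.47, with exact p = 0.0857 (adjusted 0.229) between the injured groups, but these are the few that took a hashtag.

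**Figure D1:**
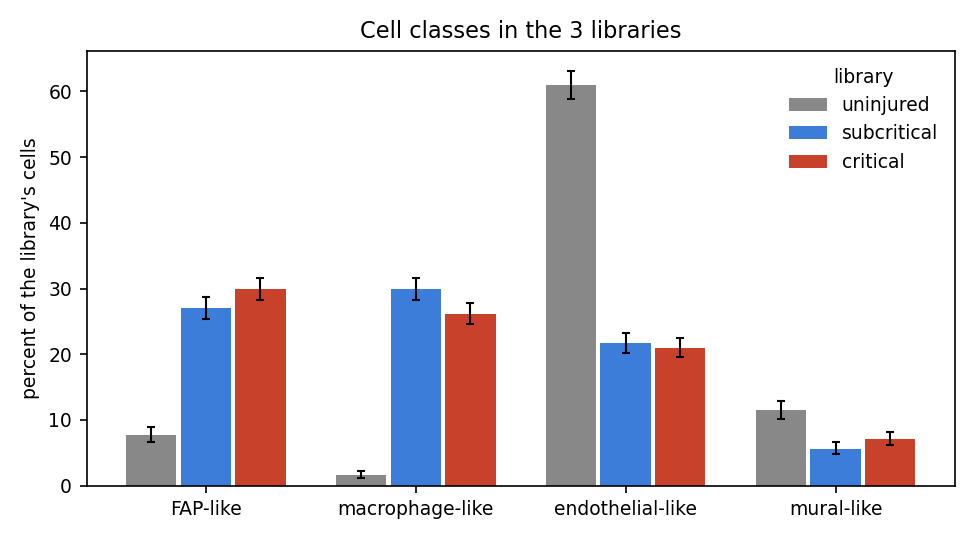
Bars give the percent of each library's kept cells (vertical axis) in 4 classes for the uninjured, subcritical and critical libraries, with 95% exact binomial intervals. FAP-like and macrophage-like cells fill 27.0% and 29.9% of the subcritical and 29.9% and 26.2% of the critical library, against 7.78% and 1.59% of the uninjured.

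Critical against subcritical FAP-like cells ask which fibroblast programme goes with the injury that scars. At this time point both wounds were already deep in the scar-matrix programme. Over the whole class its lists stood near 0 between the wounds, but within cluster 13 the matricellular median was 0.31. Wnt-pathway genes, several of them secreted Wnt inhibitors, were lower and interferon-response genes higher in the critical library. Other classes of the 2 libraries share some differences: the 20 ribosomal and mitochondrial genes called in macrophages had the same sign here, with a median of 0.98, and interferon medians were also positive in macrophages (0.24) and endothelium (0.34). The comparison rests on 907 critical and 749 subcritical cells with medians of 2540 and 1964 UMIs. The resting cluster 13 held 231 of each, and so a smaller part of the critical class.

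Wnt-pathway genes were lower, with 1 of 16 members higher, a median log2 fold of −0.31 and percentile 0.00 among 10000 random lists matched on expression. Dkk2, a secreted Wnt antagonist, was at 34.8 CPM (counts scaled to the library's total in that class) against 77.6, log2 −1.14 (−1.57 to −0.75). The secreted frizzled-related proteins Sfrp4, Sfrp1 and Sfrp2, which bind Wnt ligands, were at −0.57 (−0.76 to −0.39), −0.45 (−0.61 to −0.30) and −0.39 (−0.49 to −0.30). Parenchymal fibroblast genes, which mark the resting interstitial state, had a median of −0.21 (3 of 16 higher, percentile 0.02). The opioid precursor Penk was at −0.73 (−1.09 to −0.40) and the chemokine Cxcl14 at −0.56 (−0.69 to −0.44). Gdf10, a BMP-family ligand, was at −0.53 (−0.91 to −0.16) and Ltbp4, which tethers latent TGF-beta in elastic fibres, at −0.57 (−0.77 to −0.37). Within cluster 13 alone the Wnt median was −0.25 and the parenchymal median −0.12. Complement genes had a median of −0.17 (1 of 12 higher, percentile 0.98), with C2 at −0.64 (−1.01 to −0.29), but −0.06 within cluster 13 and 0.088 with coarser clusters. The gelatinase Mmp2 was at −0.42 (−0.50 to −0.35), although its list of matrix proteases and inhibitors had a median of 0.06 (12 of 20, percentile 76.5).

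The matrix lists stood near 0. Fibrillar collagen and crosslinking genes had a median of −0.02 (8 of 19 higher, percentile 8.93), the TGF-beta pathway 0.02 (11 of 22, percentile 55.7) and basement membrane genes −0.11 (3 of 14, percentile 2.61). Matricellular and activated-fibroblast genes had 0.04 (14 of 23, percentile 83.8), with 0.20 for a hashtag share of 70%, 0.21 by marker score and −0.06 with coarser clusters. Within these lists the critical library was higher for Aspn, a small proteoglycan of scar and tendon, at 0.64 (0.50 to 0.80), and for the smooth muscle actin Acta2 of myofibroblasts at 0.42 (0.28 to 0.57). The transcription factor Runx1 was at 0.39 (0.20 to 0.59) and the basement membrane linker Nid1 at 0.46 (0.32 to 0.59). The collagen crosslinker Loxl2 and the collagen chaperone Serpinh1 were at 0.33 (0.19 to 0.48) and 0.23 (0.18 to 0.28). The laminin chain Lamb2 was lower, at −0.44. Interferon-response genes stood at 0.27 (18 of 20 higher, percentile 99.8), with the ubiquitin-like Isg15 at 159 against 99.1 CPM, log2 0.67 (0.41 to 0.95). Proliferation genes had 0.24 (13 of 20, percentile 98.1; −0.22 with coarser clusters; Stmn1 0.60, 0.15 to 1.10) and dissociation and stress genes 0.15 (12 of 18, percentile 99.7; Egr1 0.55, 0.37 to 0.74).

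Osteopontin (Spp1), a matrix-bound cytokine of scars, was at 190 against 446 CPM, log2 −1.23 (−1.40 to −1.06). The 10 highest of 749 subcritical cells held 76.4% of its counts, however, and without the 10 highest cells of each library it stood at 95.6 against 108 CPM, log2 −0.17. Cxcl2, a neutrophil attractant, was at 58.5 against 16.4 CPM, log2 1.77 (1.23 to 2.50), with 53 critical and 18 subcritical cells positive, but at −0.02 with classes drawn by marker score. Insulin-like growth factor 2 (Igf2), an embryonic growth factor, was at 0.69 (0.34 to 1.07) and the fatty-acid carrier Fabp4 at 1.11 (0.65 to 1.65), with the adipogenic list at 0.11 (8 of 15, percentile 89.1).

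The tenogenic and chondrogenic list had a median of −0.24 (5 of 15, percentile 0.23). The cartilage matrix protein Comp was at −0.77 (−0.94 to −0.61) and the tendon gene Tnmd at −0.46 (−0.67 to −0.26), which turned to 0.09 and 0.12 where coarser clusters or marker scores drew the classes. Near 0 were universal progenitor fibroblast genes at −0.06 (2 of 16, percentile 13.4), chemokines and cytokines at −0.04 (7 of 16, percentile 24.4). So were growth factors and antagonists at 0.03 (11 of 20, percentile 55.7), and hypoxia and glycolysis at 0.10 (13 of 18, percentile 91.1; −0.11 within cluster 13). Macrophage lists read in FAP-like cells gave medians of 0.52 for pro-inflammatory (5 of 5, percentile 99.6; −0.04 by marker score), 0.15 for alternatively activated and resident (6 of 9, percentile 89.0) and 0.10 for scar-associated and lipid-handling genes (10 of 16, percentile 95.7). They gave −0.02 for lysosome and phagocytosis (8 of 17, percentile 30.4) and −0.31 for antigen presentation (2 of 13, percentile 0.01). Endothelial activation and angiogenesis had 0.02 (6 of 11, percentile 52.0), myogenic genes 0.08 (6 of 10, percentile 75.9), muscle fibre transcripts −0.05 (3 of 6, percentile 34.4) and fibroblast transcripts −0.04 (4 of 10, percentile 7.22). Immune transcripts, which in these cells measure RNA of other cells, had −0.41 (2 of 9, percentile 0.00), with Cd74 at −0.87 (−1.12 to −0.63) and Lyz2 at −0.53 (−0.72 to −0.36), and no red blood cell transcript was measured.

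Critical and subcritical FAP-like cells against uninjured ones ask what either wound does to fibroblasts. In uninjured muscle the class held quiescent, complement-rich interstitial fibroblasts, and in both wounds it held cells rich in transcripts of scar matrix. The uninjured class, 166 cells with a median of 3722 UMIs, fell almost wholly in cluster 13 (154 cells). Most injured FAP-like cells fell in cluster 17 (391 subcritical and 520 critical cells, 3 uninjured) and 231 of each injured library in cluster 13.

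The matricellular and activated-fibroblast list had medians of 2.81 in the critical and 2.89 in the subcritical library, each with 21 of 23 members higher. Cthrc1, a collagen-associated protein of scar-forming fibroblasts, was at 1097 and 1407 CPM against 12.4 in uninjured cells, log2 6.36 (5.49 to 7.69) and 6.72 (5.85 to 8.05). Periostin (Postn), which organises collagen in wounds, was at 5618 and 4689 CPM against 117, log2 5.57 (5.26 to 5.93) in the critical library. The scar-fibroblast marker Lrrc15 was at least 41.3-fold and at least 35.0-fold higher, Ddah1 at least 37.5-fold and 35.0-fold, the tendon transcription factor Scx at least 20.2-fold and 29.4-fold, and the tenascin Tnn at least 17.8-fold and 22.4-fold. The metalloprotease Adam12, with 2 uninjured counts, was at 5.50 (4.04 to 8.95) and 5.30 (3.83 to 8.75), and the growth factor Ptn at 5.80 and 5.58. Collagen and crosslinking genes had medians near 1 (17 of 19 higher in the critical) and 0.81 (18 of 20 in the subcritical library). The crosslinker Lox was at 2.83 and 2.87, Col11a1 at 2.63 and 2.90, the prolyl hydroxylase P4ha3 at 2.45 and 2.59, and Col1a1 at 24672 and 26012 CPM against 6047. Timp1, which blocks matrix proteases, was at 2.67 and 2.69. Of the genes of fetal mesenchyme, the Notch-like Dlk1 was at 4.50 and 4.69 and Igf2 at 3.70 (2.52 to 5.79) and 3.01 (1.80 to 5.11). Igf1, a growth factor for myoblasts, was at 1.05 and 1.26, Tgfb3 at 1.92 and 1.75, the tendon proteoglycan Fmod at 3.05 and 3.31, Spp1 at 2.81 (2.16 to 3.65) and 4.04 (3.4 to 4.88), and Isg15 at 3.28 and 2.61.

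Lower in both wounds was the resting programme. All 12 complement genes measured were lower in both libraries, with medians of −1.20 and −1.03. The terminal component C7 was at 11.5 and 18.9 CPM against 661, log2 −5.73 and −5.05. Universal progenitor genes had a median of −1.60 in the critical library (1 of 16 higher), with the progenitor surface protein Cd34 at 284 and 295 CPM against 1161, log2 −2.03 and −1.97. Parenchymal genes had −1.34 and −1.12 (1 of 16), with Gdf10 at −2.87 and −2.35. The actin-severing Gsn was at 2313 and 3103 CPM against 37182, log2 −4.01 and −3.58, and the methyltransferase Inmt at −5.45 and −5.98. The eosinophil attractant Ccl11 was at −3.08 and −3.03, the lubricin gene Prg4 at −3.68 and −3.59, and the proteoglycan Dcn at −2.0 and −1.89. In the critical library the fibroblast glycoprotein Myoc was at 219 against 3050 CPM, log2 −3.79, and the collagen processing enhancer Pcolce2 at −3.58, and in the subcritical library the interferon-inducible Ifi205 was at −3.73 and the calcium-binding S100a4 at −3.61. Lama2, the laminin chain that muscle fibres anchor to, was at −1.55 and −1.50, and Lamb2 at −2.10 and −1.66.

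Proliferation genes had medians of 2.25 and 2.49 (19 of 19 and 14 of 15 higher; 1.93 and 1.64 with genes uncounted in 1 library at their bound). Interferon genes had 1.24 and 0.94 (14 of 17, 14 of 18), hypoxia and glycolysis 0.60 and 0.36, and tenogenic genes 0.75 and 0.74. Medians were small for the TGF-beta pathway at 0.00 and 0.04 and basement membrane genes at −0.38 and −0.41, which turned to 0.23 and 0.10 with coarser clusters and 0.04 and 0.14 within cluster 13. The Wnt list had −0.53 and 0.19, with Wnt11 at −2.69 and −1.92 and Sfrp1 at 0.93 and 1.38. Immune transcripts also stood higher, at 3.85 and 4.36 (3.23 and 3.78 with bounds), with Lyz2 at 5.70 (4.24 to 9.15) and 6.24 (4.78 to 9.69), so macrophage transcripts are counted in these droplets. Within cluster 13 alone, Cthrc1 was at 6.68 in the critical library, the matricellular median at 1.65 and 1.52 and Gsn at −2.18 and −1.93. There, medians of universal progenitor (−0.02 and −0.22), parenchymal (−0.14 and −0.17) and complement genes (−0.09 and −0.06) were nearer 0 than in the whole class.

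**Figure D2:**
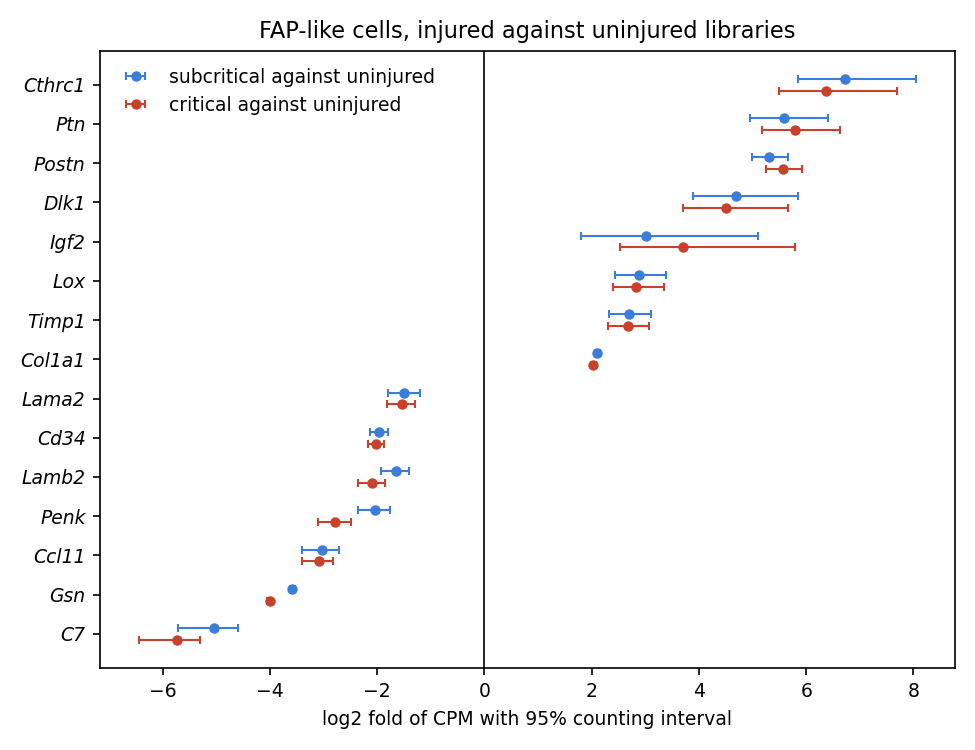
Log2 fold of CPM against uninjured FAP-like cells (horizontal axis) for 15 genes in the subcritical and critical libraries, with 95% counting intervals. Cthrc1 lies at 6.72 and 6.36 and C7 at −5.05 and −5.73, and each of the 15 genes lies on the same side of 0 in both libraries.

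Critical against subcritical macrophage-like cells ask whether macrophages differ between a wound that scars and one that heals. None of the lists for resident, scar-associated, pro-inflammatory, lysosomal or antigen-presenting macrophages passed the test, which does not show that these programmes were alike. The genes that did pass were mostly of the ribosome and the mitochondrial genome. Of 4023 genes, 39 passed an adjusted p of 0.05 in edgeR with 4 animals per group, 19 higher and 20 lower in critical animals, and 38 passed in DESeq2, 32 of them the same genes. Among the 39, 11 were ribosomal (2 higher, 9 lower) and 9 of the 11 mitochondrially encoded genes tested were higher. Rps29 was at log2 −1.29 ± 0.108 (SE, adjusted p = 2.28e-12) and Rps28 at −1.07 ± 0.115 (adjusted p = 9.88e-09). All 20 moved the same way in the 5 other classes of the same libraries, and with ribosomal and mitochondrial genes left out, 15 of 3920 genes passed.

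Of the other 19 genes, lower in critical macrophages were Tnfaip2, a gene induced by TNF, at 104 ± 23.1 against 202 ± 37.8 CPM (SD, n = 4), log2 −1.01 ± 0.194 (adjusted p = 0.000984). So was the RNA helicase Dhx15, at 36.1 ± 15.0 against 79.9 ± 8.18 CPM, log2 −1.07 ± 0.281 (adjusted p = 0.0426), which 8 of the other settings did not call. The respiratory chain genes Atp5k, Ndufb1-ps and Atp5md fell by 1.0, 0.78 and 0.76 log2 units (adjusted p = 0.00133, 0.0205 and 0.00482), the chaperone partner St13 by 0.92 (adjusted p = 0.00482). Hexokinase 2 (Hk2), the first step of glycolysis, fell by 1.22 (adjusted p = 0.0326), which 9 settings did not call. Higher were the calcium-binding S100a4 of migrating cells at 241 ± 92.8 against 108 ± 17.9 CPM, log2 1.27 ± 0.224 (adjusted p = 0.00136). So were the cytoskeletal kinase Peak1 at 1.15 ± 0.255, the linker histone Hist1h1e at 1.14 ± 0.271, the ribosomal-repeat transcript AY036118 at 0.61 ± 0.112 (adjusted p = 0.000452) and the chemokine Ccl4 at 0.66 ± 0.160 (adjusted p = 0.0212). Critical and subcritical animals overlapped in Ccl4 and Hk2 and in none of the other genes named here. Igfbp7, a vessel-wall gene, passed at 1.19 (adjusted p = 0.0117) but stood at −0.08 with the highest doublet scores removed, and Ccl4 and Hist1h1e were lost in 9 and 6 settings. The 19 genes had their macrophage sign in 66 of 82 folds measured in the 5 other classes. Dhx15, Atp5k, Ndufb1-ps, Atp5md, St13, S100a4 and AY036118 had it in all 5, so their changes were not particular to macrophages. Igfbp7 had the opposite sign in all 5.

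By camera with its preset correlation, proliferation genes were higher (median 0.37, 10 of 11 positive, 0 past the threshold, Pcna at 0.70 with adjusted p = 0.215; list adjusted p = 0.0170). Immune transcripts were lower (median −0.21, 1 of 10 positive, 0 past over all genes, 5 adjusted over the list alone; adjusted p = 0.0141, Lyz2 at −0.29). With an estimated correlation neither held (adjusted p = 0.732 for both). The rest did not pass. Scar-associated and lipid-handling genes had a median of −0.12 (3 of 18 positive, adjusted p = 0.182; Apoe −0.28) and interferon genes 0.24 (11 of 14, adjusted p = 0.218; Rtp4 0.70). Antigen presentation had −0.09 (1 of 14) and lysosome −0.09 (7 of 19), each with adjusted p = 0.218. Resident genes had 0.03 (7 of 14, adjusted p = 0.633; Mrc1 0.45), and hypoxia −0.03 (3 of 10, adjusted p = 0.295). Pro-inflammatory genes had a median of −0.06 with a mean of 0.16 (4 of 8, 1 past the threshold, 2 adjusted over the list alone, adjusted p = 0.423).

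**Figure D3:**
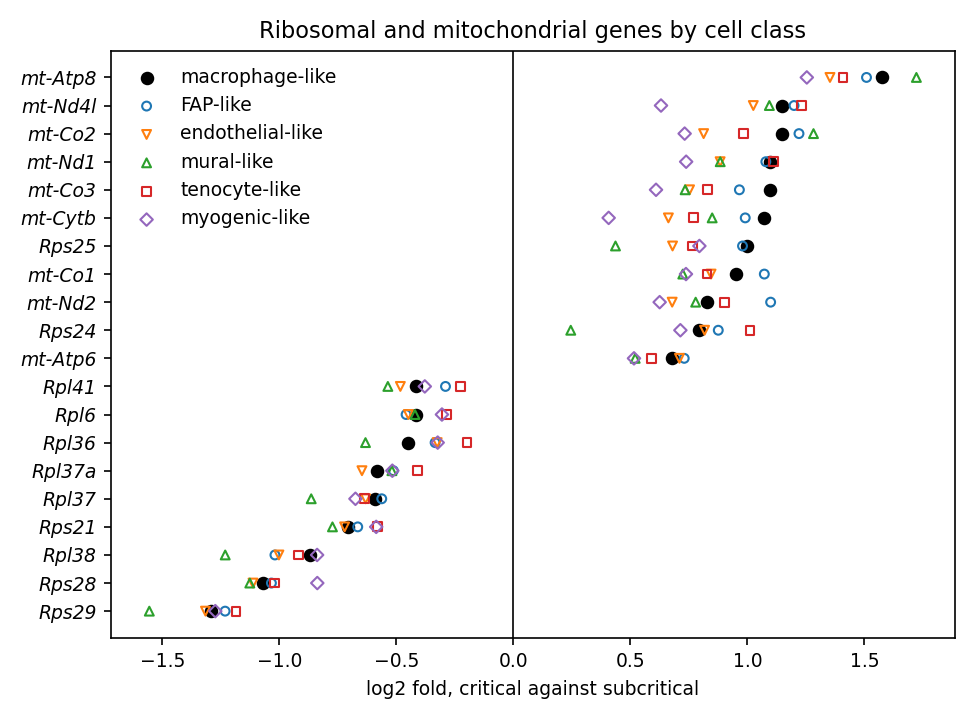
Log2 fold, critical against subcritical (horizontal axis), of the 20 ribosomal and mitochondrial genes that passed in macrophage-like cells, with macrophage-like cells as filled and 5 other classes as open symbols. All 100 folds of the other classes have the sign seen in macrophage-like cells.

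Against uninjured muscle, macrophages of both wounds had higher lipid-handling and lysosomal genes and lower genes of resident macrophages. Only 34 macrophage-like cells came from the uninjured library, so these are values of 1 library per group with no test. Of the 34, 23 fell in cluster 15, which held 237 subcritical and 306 critical cells, against 3 in cluster 2 (166 and 206). Spp1 was at 4241 CPM in the critical and 3120 in the subcritical library against 10.1 (1 count), log2 8.58 (6.24 to 14.0) and 8.14 (5.79 to 13.6). The bone-resorption phosphatase Acp5 was at least 15.7-fold and 15.3-fold higher, Mfge8, which tags dying cells for uptake, at least 13.1-fold and 10.0-fold, the collagenase cathepsin Ctsk at least 7.58-fold and 9.61-fold and the integrin Itgax at least 3.80-fold and 4.27-fold. The elastase Mmp12, with 1 uninjured count, was at 4.34 (1.98 to 9.78) and 3.97 (1.61 to 9.41). The lipid carriers Fabp5 and Apoe were at 3.08 and 3.17 and at 2.06 and 2.27, the cathepsin Ctsl at 3.92 and 3.57, Gpnmb at 3.26 in the critical library, Cxcl2 at 3.13 and 3.06, and Igf1 at 1.81 and 1.90. Scar-associated genes had medians of 1.85 and 1.70 (19 of 20 and 20 of 20 higher; 1.67 and 1.59 with bounds), lysosome genes 1.22 and 1.13, and resident genes −1.10 and −1.59 (5 of 21 and 4 of 19 higher). Lyve1, the hyaluronan receptor of vessel-side macrophages, was at 7.53 and 14.7 CPM against 757, log2 −6.47 and −5.59. The cell-debris receptor Timd4 was at least 73.7-fold lower in the critical library, with the haemoglobin receptor Cd163 at −4.30, the lectin Mgl2 at −4.10 and the complement receptor Vsig4 at least 49.1-fold lower. In the subcritical library Retnla, an interleukin-4 target, was at 166 against 4711 CPM, log2 −4.82, and Cd209f at least 37.0-fold lower.

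Pro-inflammatory genes had medians of 1.32 and 1.31 (10 of 13 higher; 0.65 and 0.72 with bounds) and interferon genes 2.40 and 1.73 (17 of 19, 15 of 19; 0.91 and 0.54 with bounds). The interferon regulator Irf7 was at least 4.84-fold and 4.29-fold and Cxcl10 at least 4.21-fold and 4.05-fold higher, and antigen presentation had −0.26 and −0.33. Matrix proteases and inhibitors had 2.44 and 0.64, but 0.02 in both with bounds. Of 2 genes that platelets express, Nrgn was at least 111-fold lower in the subcritical library and Gp9 at least 29.5-fold and 24.7-fold lower. The collagen gene Col1a1 was at least 9.53-fold and 15.3-fold higher. FAP-like cells of the same libraries are rich in it, so these counts cannot be taken as the macrophages' own.

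Endothelial-like cells were tested with 3 critical, 3 subcritical and 4 uninjured animals. In both wounds the basement membrane list rose and the adipogenic list fell. The class drew on different clusters: 795 of 1301 uninjured cells lay in cluster 6 and 39 in cluster 5, against 112 and 284 of 602 subcritical and 195 and 217 of 636 critical cells. Against uninjured animals, 397 of 2249 genes passed in critical (218 higher, 179 lower; 247 in DESeq2) and 425 in subcritical animals (241 higher, 184 lower; 280 in DESeq2). Without subcritical replicate 4, 234 passed in the latter. Ribosomal genes made up 49 of the calls in critical (41 higher, 8 lower) and 61 in subcritical animals (57 higher, 4 lower).

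Basement membrane genes rose in both, with medians of 1.05 and 1.04 and 7 and 6 of 10 members past the threshold upward (8 and 7 adjusted over the list alone). Col18a1, whose fragment is endostatin, was at 315 ± 121 CPM (SD, n = 3) in critical against 12.4 ± 12.9 (n = 4) in uninjured animals, log2 4.24 ± 0.476 (adjusted p = 9.55e-08), and 3.97 in subcritical animals. Col15a1, laid down by sprouting vessels, was at 666 ± 143 in critical and 770 ± 59.5 in subcritical against 82.2 ± 46.9, log2 2.82 ± 0.226 (adjusted p = 4.83e-14) and 3.01 (adjusted p = 1.62e-14). The main basement membrane collagen Col4a1 rose by 1.10 and 1.40 and the collagenase Mmp14 by 4.12 and 4.08, although it ran from 0 to 205 CPM in subcritical animals, overlapping the uninjured ones, and fibroblast transcripts rose in the same cells (3.48 and 3.34). The list of endothelial activation and angiogenesis had medians of 0.62 and 0.79 and passed with the preset correlation (adjusted p = 0.0151 and 0.00235) but not with an estimated one (adjusted p = 0.123 and 0.0687). The fenestral protein Plvap was at 1.32 (adjusted p = 0.00904) and 1.46 and Lrg1, a promoter of vessel growth, at 1.18 and 1.54, calls that were lost without critical or subcritical replicate 4. The TGF-beta receptor Tgfbr2 rose by 2.19 and 1.72, while its list did not pass (adjusted p = 0.545 and 0.731). Adipogenic and lipid genes fell in both (medians −0.52 and −0.82, 4 of 8 past the threshold downward in each). The fatty-acid carrier Fabp4 was at 8795 ± 393 and 7540 ± 807 against 32114 ± 6197 CPM, log2 −1.86 ± 0.115 (adjusted p = 2.22e-13) and −2.09 (adjusted p = 3.19e-14). The fatty-acid transporter Cd36 was at −0.94 and −1.18 and the lipase Lpl at −0.83 and −1.27. Also lower were the T-cell attractant Cxcl9, at −4.25 ± 0.623 (adjusted p = 9.23e-07) and −2.48 (adjusted p = 0.000195), and the capillary gene Timp4, at −2.10 and −2.54. Interferon genes passed in critical animals (4 of 11 past the threshold, list adjusted p = 0.00999, but 0.0956 with an estimated correlation) and not in subcritical ones (median 0.26, adjusted p = 0.348). Isg15 was at 1.16 and 0.91 and Irf7 at 1.51 in critical animals (adjusted p = 0.00028). Between the wounds directly the list did not pass (median 0.34, 9 of 11 positive, adjusted p = 0.102, and 0.470 with an estimated correlation).

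The basement membrane and adipogenic calls held with an estimated correlation (adjusted p = 0.0178 and 0.0255, and 0.0256 and 0.0144), as did proliferation in subcritical animals (adjusted p = 0.0152). Proliferation in critical animals (adjusted p = 0.302) did not hold. Collagen genes passed too, at 3.41 and 3.18, but fibroblast transcripts and immune transcripts (4.32 and 3.63) rose with them. Lyz2 stood at 4.32 and 3.46 and the complement gene C1qb of macrophages at 5.60 and 5.62, so the collagen counts cannot be taken as the endothelium's own.

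Between the wounds, 12 of 2249 genes passed in endothelial-like cells, 2 higher and 10 lower in critical animals (7 in DESeq2), and 9 of them were ribosomal or mitochondrial. The other 3 all serve dividing cells and were lower. Stmn1, which takes microtubules apart, was at 147 ± 123 against 407 ± 117 CPM (SD, n = 3), log2 −1.66 ± 0.367 (adjusted p = 0.0176). The chromatin protein Hmgb2 was at 193 ± 68.6 CPM, log2 −1.45 ± 0.286 (adjusted p = 0.00186). The histone H2afz was at 760 ± 290 against 1303 ± 152, log2 −0.85 ± 0.194 (adjusted p = 0.0167). None of the 3 passed in DESeq2. The proliferation list had a median of −1.45 with 0 of 7 members positive, 2 past the threshold and 4 adjusted over the list alone (adjusted p = 1.43e-12, and 0.0944 with an estimated correlation). Against uninjured animals it stood at 0.99 in critical (1 of 7 past) and 2.49 in subcritical animals (7 of 7), where Birc5 and Cdk1, which drive mitosis, rose by 3.48 and 3.37.

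Dividing cells were also counted directly, as cells with at least 2 of the mitosis genes Mki67, Top2a, Cdk1, Birc5 and Ube2c after thinning each cell to 1074 UMIs. Dividing macrophage-like cells were more common in the critical library, at 8.24% (6.00 to 11.0) against 3.6% (2.07 to 5.77). Dividing endothelial-like cells were more common in the subcritical, at 8.03% (4.98 to 12.1) against 3.69% (1.92 to 6.36) in the critical and 0.218% in the uninjured library. Without thinning the shares were 8.19% and 4.10%, and 7.31%, 3.30% and 0.538%. Thinning left out 284 critical and 385 subcritical macrophage-like and 311, 353 and 383 critical, subcritical and uninjured endothelial-like cells. Per animal the macrophage-like share was 7.71% ± 2.51 against 3.21% ± 3.06 (SD, n = 4, exact two-sided permutation p = 0.0571), and 14.8% ± 1.87 against 7.21% ± 2.44 for at least 1 marker (exact p = 0.0286). Without thinning it was 7.91% ± 2.97 against 4.27% ± 0.894 (exact p = 0.143). The unthinned endothelial-like share was 3.04% ± 0.377 against 11.0% ± 1.80 (n = 3), with exact p = 0.1, the smallest that 3 against 3 animals allow. That share is of tagged cells only, and over all cells of the class the gap was smaller (3.30% against 7.31%). FAP-like cells outside the dividing cluster 18 were at 0.677% (0.220 to 1.57) and 0.528% (0.109 to 1.54) in critical and subcritical libraries, with 168 and 181 cells left out, and unthinned at 2.76% and 1.74%. In uninjured FAP-like cells, 0 of 151 allows up to 1.99% at 3 counts. Counting in cluster 18, which was kept out of every class and held 1.22%, 0.972% and 0% of the critical, subcritical and uninjured cells, both stood at 3.87%. As a background, 0 of 201 uninjured mural-like cells were positive (up to 1.49% at 3 counts), against 8 of 156 critical and 2 of 82 subcritical ones, with median depths of 3317.5, 1452.5 and 1121 UMIs.

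**Figure D4:**
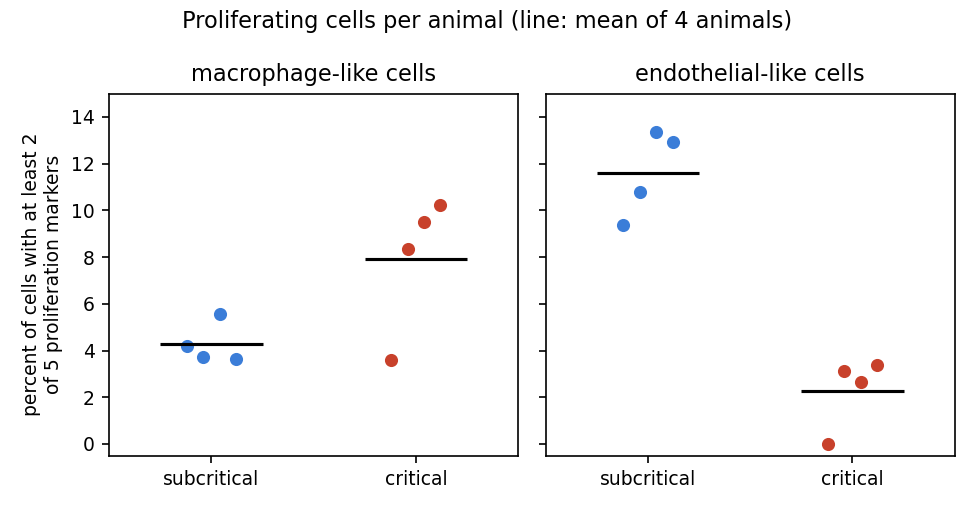
Each point is 1 animal's percent of cells with at least 2 of 5 mitosis genes, not thinned (vertical axis), in macrophage-like and endothelial-like cells of the subcritical and critical groups, and the line is the mean of 4 animals. Endothelial-like shares run from 9.38% to 13.3% in subcritical and from 0% to 3.37% in critical animals, and macrophage-like shares from 3.62% to 5.56% and from 3.61% to 10.2%.

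In edgeR 0 of 137 antibodies passed between critical and subcritical macrophage-like cells, with 16 at an unadjusted p under 0.05, and 3 of 138 passed in DESeq2. F4/80, the macrophage marker, was at log2 −0.55 and Tim-4, the debris receptor, at 0.46 (adjusted p = 0.106 for both in edgeR). The mannose receptor CD206 (CD206_MMR__TSC in the panel) was at 6.22, 5.52 and 8.74 counts per cell in critical, subcritical and uninjured macrophage-like cells once antibody aggregates were left out. On FAP-like cells, which were not tested, the PDGF receptor CD140a that defines FAPs was at 0.667 (0.615 to 0.722), 0.901 (0.834 to 0.972) and 0.428 (0.334 to 0.540) counts per cell against 0.115, 0.172 and 0.169 for the highest isotype control. The stem-cell antigen Sca-1 was at 0.326, 0.522 and 0.675.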

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

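Of the tests in this part, only the comparison of deeper and shallower cells within a library was written before its result was seen. The other tests of explanations, and the splits of the animals, were chosen after the results they bear on had been seen.

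The genes that separated critical from subcritical macrophages were in good part not macrophage genes. The 20 ribosomal and mitochondrial genes called had the macrophage sign in 100% of their 100 folds in FAP-like, tenocyte-like, mural-like, endothelial-like and myogenic-like cells, with a median of 0.77 against 0.91 in macrophages, so a difference that every class of the 2 libraries shares may account for them. The 19 other genes had it in 80.5% of 82 folds, just past the 80% set for it, with a median of 0.54 against 0.92, so the same reading could hold for part of their change. Depth as it varies between cells of a library is argued against for the mitochondrial genes. Of the folds of deeper against shallower macrophages within a library, only 20% (8 of 40) had the sign of the critical fold, and none of these was mitochondrial. For ribosomal genes the signs were mixed, with all 6 matching folds of the subcritical library among them. The split cannot speak to a difference in depth between the 2 libraries. Whether the shared difference comes from library preparation or from the wound itself cannot be told apart, since each group is 1 library.

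Spp1 was lower and Cxcl2 higher in FAP-like cells of the critical library. Lyz2 in FAP-like cells would bring at most 81.6 CPM of Spp1, against 446 CPM seen in the subcritical library (lower bound 414), and 15.4 CPM of Cxcl2, against 58.5 CPM in the critical (lower bound 49.5), so macrophage RNA does not reach either level. Without the 10 highest cells of each library Spp1 stood at log2 −0.17, so a few cells may carry its difference, and those 10 subcritical cells had a Lyz2 total of 1 count. The 10 highest cells for Cxcl2 had Lyz2 totals of 86 in the subcritical and 14 in the critical library, so macrophage RNA may add to the subcritical level. For Cxcl2 the 10 highest cells are most of the 18 positive subcritical cells, so its value without them, 2.04, decides nothing, it stood at −0.02 with classes by marker score, and a few cells or a true difference both stay open.

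The share of dividing macrophages, set against that of dividing endothelium, differed between the wounds: every critical animal had a larger macrophage-like than endothelial-like share and every subcritical animal the reverse. In these tagged cells endothelium separated the animals more clearly, since in macrophages critical replicate 1 (3.61%) lay level with the lowest subcritical animal (3.62%). Its endothelial-like share of 0% rests on 12 cells. Over all cells of the libraries, not thinned, the 2 classes differed by similar amounts: 8.19% in critical against 4.10% in subcritical macrophages, and 3.30% against 7.31% in endothelium. With at least 10 cells per animal the difference of the shares was 5.63% ± 1.55 in critical and −7.34% ± 1.72 in subcritical animals (SD, n = 4), 12.97 points apart (exact two-sided permutation p = 0.0286, the smallest possible), and with at least 20 cells 13.5 points apart (n = 3, exact p = 0.1, the smallest for 3 against 3). A single shift of both classes could not give that gap, which is the pattern itself rather than a separate test of it, and 0 directions turned over 8 ways of drawing cells and classes. Depth is argued against for endothelium, where critical cells were the deeper (median 1090.5 against 951 UMIs) and had the lower share in all 3 animals with enough cells, and as the whole cause for macrophages, where thinning to equal depth left a difference (8.24% against 3.6%, exact permutation p per animal 0.0571, and with at least 1 marker 14.8% ± 1.87 against 7.21% ± 2.44, exact p = 0.0286). A candidate explanation is that endothelium of the larger wound divides less, a hypothesis found on the same animals and not tested further. Whether it extends to vessels as a whole cannot be told. Thinned mural-like cells were positive in 8 of 156 critical (5.13%, 2.24 to 9.85) and 2 of 82 subcritical cells (2.44%, 0.297 to 8.53). These intervals overlap, and shares of so few positive cells were not tested between animals. The pooling of each group in 1 library stays open.

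Chance is argued against for the number of genes past the threshold in macrophage-like cells between the wounds (39, highest other split 9), in endothelial-like cells of critical (397, highest other 58) and subcritical animals (425, highest other 41) against uninjured ones, and in cluster 1 between the wounds (8, highest other 2), where 1 of 35 splits, the real one, gave as many. That is the smallest share 35 splits allow. The real split is also the split between libraries, so these counts cannot tell an effect of the wound from a difference between libraries. For endothelial-like cells between the wounds 10 splits are too few for a share under 0.05 (12, highest other 1). For antibodies 0 passed (highest other split 0), which all 35 splits must match, so chance is not excluded and this count cannot speak to it.

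Among 109 groups of 4 animals, 11 held 1 animal far from the other 3, where chance gives about 1 in 20 groups, or 5.45. That rate does not hold for 3 of the 11, in which 1 or 2 cells of 1 animal stand against 0 in the others. Tenocyte-like cells were 0.178% of tagged cells (1 cell) in 1 uninjured animal and 0% in the others, and myogenic-like cells 0.714% (1 cell) in 1 uninjured animal and 0% in the others. Neutrophil-like cells were 2.88% in 1 subcritical animal against 0.333% to 0.467% in the rest, and 0.506% (2 cells) in 1 critical animal against 0%. Cluster 1 took 12.97% of 1 uninjured animal's tagged cells against 3.94% to 4.88%.

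In macrophage-like cells Dhx15 was at 67.7 CPM in 1 subcritical animal against 82.8 to 85.3, S100a4 at 80.9 in 1 subcritical animal against 114 to 119 and at 378 in 1 critical animal against 176 to 209, and Rps28 at 1761 in 1 subcritical animal against 2381 to 2418. In endothelial-like cells of uninjured animals Stmn1 was at 16.3 CPM in 1 animal against 78.2 to 82.8 and Pnpla2 at 342 against 164 to 188.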

How the results depend on the processing

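Settings chosen after the data were seen, and so tests not planned, were the removal of the highest doublet scores, the FAP-like class without cluster 9, with cluster 18 or within cluster 13, equal weight per cell, ribosomal and mitochondrial genes left out, aggregates left out, and the highest cells left out. The others were set before the data were examined.

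Named genes with a test kept their direction and their side of the threshold in 1286 comparisons with an alternative. They lost the call in 97, gained one in 5 and turned in 1, Igfbp7 of macrophages, at −0.083 with the highest doublet scores removed. Named genes without a test stayed within their interval in 1276 comparisons and left it in 643, and 7 turned. In 1 of these Cxcl2 of FAP-like cells between the wounds stood at −0.022 with classes by marker score. Tnmd stood at 0.088 at Leiden 0.4 and 0.12 by marker score, and in macrophages against uninjured cells Ube2c at −1.46 and −1.57 and Cd74 at 0.045 and 0.20 in the critical and subcritical library by marker score. The marker score puts other cells in each class, and beyond that the cause was not tested.

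With ribosomal and mitochondrial genes left out, 15 genes were called in macrophages, 1 in endothelial-like cells and 1 in cluster 1 between the wounds. All of these were also called with those genes kept in. Some other genes lost their call, and the cause was not tested. DESeq2 called 7 in endothelial-like cells between the wounds, 247 and 280 in critical and subcritical against uninjured animals, 5 in cluster 1 and 3 antibodies in macrophages. A hashtag share of 70% called 257 in critical against uninjured endothelial-like cells, with 2 against 3 animals. Leaving out 1 animal at a time gave 27 to 57 genes in macrophages, 8 to 18, 266 to 380 and 234 to 417 in endothelial-like cells (between the wounds, critical and subcritical against uninjured), 6 to 11 in cluster 1 and 0 to 1 antibodies. The 234 is without subcritical replicate 4, and the 1 antibody, Gr-1, without critical replicate 4. Stmn1, Hmgb2 and H2afz of endothelial-like cells lost their calls in 8, 5 and 9 settings. Against uninjured animals, Plvap and Lrg1 stood at 1.21 and 0.945 without subcritical replicate 4 and at 1.24 and 0.897 without critical replicate 4, and lost their calls. In macrophages Atp5md (−0.712) lost its call without critical replicate 2, St13 (−0.79) without critical replicate 4, and Peak1 without critical (1.03) or subcritical replicate 3.

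The matricellular median of FAP-like cells between the wounds (0.04) stood at 0.20 with a hashtag share of 70%, 0.13 with the stricter cell filter, −0.058 at Leiden 0.4, 0.21 by marker score, 0.13 with cluster 18 and 0.31 within cluster 13. Against uninjured cells it stood at 2.11 and 2.46 at Leiden 0.4, 2.00 and 2.02 by marker score, and 1.65 and 1.52 within cluster 13, in the critical and subcritical library. At Leiden 0.4 cells with Postn and Ptn joined a cluster of tenocyte name, which takes them out of the class. Other FAP-like list medians turned. Between the wounds these were complement (0.088) and proliferation (−0.22) at Leiden 0.4, hypoxia (−0.11) within cluster 13 and pro-inflammatory genes (−0.037) by marker score. In critical against uninjured cells they were basement membrane (0.23) and angiogenesis (0.36) at Leiden 0.4, and both (0.042 and 0.49) within cluster 13. In subcritical against uninjured cells they were basement membrane (0.10) at Leiden 0.4, and basement membrane (0.14), adipogenic (0.17) and angiogenesis (0.092) within cluster 13. The cause was not tested.

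In macrophages against uninjured cells the scar-associated median stood at 2.76 and 2.54 by marker score and 2.23 and 2.35 with equal weight per cell, in the critical and subcritical library, and at 1.55 in the subcritical with a pseudocount of 10 CPM. By marker score, universal progenitor (−0.25 and −0.81), proliferation (−1.56 and −1.87) and hypoxia medians (−0.24 and −0.28) turned. With the highest doublet scores removed, so did universal progenitor (−0.38 and −0.26), basement membrane in the critical (−0.89), and parenchymal (−0.20) and tenogenic medians (−1.65) in the subcritical library. Only 34 uninjured cells bear these values, and the cause was not tested.

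For the list calls of macrophages between the wounds, an estimated correlation gave adjusted p = 0.732 for proliferation and for immune transcripts, and fry 0.655 and 0.289 (over all alternatives 0.289 to 0.732). Over all tested classes, list tests kept their side in 159 comparisons with an alternative, gained a call in 6 and lost one in 9.

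FAP-like cells were 23.2% of the subcritical and 25.5% of the critical library with a hashtag share of 70%, 28.1% of the critical with the stricter filter, 14.4% and 13.5% at Leiden 0.4, and 9.79%, 30.7% and 33.9% of the uninjured, subcritical and critical library by marker score. Of non-immune cells they were 42.1% and 43.0% of the injured libraries. Macrophage-like cells were 2.53% of the uninjured library by marker score, 26.3% of the subcritical with the stricter filter and 28.1% at Leiden 1.5, and 13.1%, 83.3% and 86.1% of immune cells in the uninjured, subcritical and critical library. Endothelial-like cells were 69.4%, 33.8% and 30.2% of non-immune cells. Differences in tagged cells between critical and subcritical animals turned for FAP-like cells at Leiden 0.4 (−0.022 points), for macrophage-like cells with the stricter filter (0.689, and −5.35 to 0.266 leaving out 1 animal), and for endothelial-like cells with a hashtag share of 70% (−0.865), the stricter filter (−2.68) and leaving out 1 animal (−2.19 to 3.01).

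Dividing FAP-like cells were 1.74% and 2.76% of the subcritical and critical library without thinning, 4.75% and 5.82% with at least 1 marker, and 3.87% in each with cluster 18. In macrophages the difference between the wounds rose to 7.62 points with at least 1 marker and reached the smallest exact permutation p.

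For FAP-like cells, and for macrophages against uninjured ones, DESeq2, RLE size factors, no low-count filter, only the 2 groups, a minimum of 10 cells and leaving out 1 animal were not run, because few of their cells were assigned to animals, and likewise for the FAP-like proliferating share and surface proteins. A test of FAP-like cells with at least 10 cells per animal, 3 critical against 2 subcritical, was left out. No paired analysis was possible because each group is a separate set of animals, whose numbers only name the hashtag. Depth limits the uninjured FAP-like and macrophage-like values: 3 counts over the 34 uninjured macrophages are the floor of every fold against a gene they lack.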

Other observations

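The test of cluster 1 belonged to the tests set before the data were examined, and leaving out antibody aggregates was chosen after the values were seen.

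Cluster 1, marked by Plac8, Ly6c2, Napsa and Cd209a, genes of monocytes and of dendritic cells that descend from them, took no class name and was tested between the wounds with 4 animals per group. Of 548 genes, 8 passed in edgeR (3 higher and 5 lower in critical animals, 56 at an unadjusted p under 0.05, 5 in DESeq2). Lyz2, the lysozyme of myeloid cells, was at 5825 ± 795 against 8455 ± 830 CPM (SD, n = 4), log2 −0.52 ± 0.126 (adjusted p = 0.0477), and AY036118 rose by 1.18 ± 0.206 (adjusted p = 0.00294). The other 6 were ribosomal (1 higher, 4 lower) and mt-Co1. With ribosomal and mitochondrial genes left out, only 1 gene passed, higher in critical animals, so Lyz2 lost its call. AY036118 was also higher in critical macrophages (0.61) and in FAP-like, endothelial-like, mural-like, tenocyte-like and myogenic-like cells (0.35 to 1.46). Its rise was therefore not particular to cluster 1. Per animal the cluster took 3.94% to 12.97% of tagged cells in uninjured, 7.00% to 19.3% in subcritical and 6.58% to 19.0% in critical animals.

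Neutrophil-like cells were most common in uninjured muscle, at 5.67% of that library against 0.792% of the subcritical and 0.132% of the critical. They came with granule genes of young neutrophils, Ltf, Ngp, Lcn2 and Camp, and nearly all from a pair of animals: 14.6% (6 of 41) and 18.8% (106 of 563) of tagged cells in these, against 1.43% (2 of 140) and 0% (0 of 203) in the other two.

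Glial-like cells of nerve sheath were 5.11%, 0.468% and 1.12% of the uninjured, subcritical and critical library, and tenocyte-like cells 1.36%, 4.75% and 5.31%. Spp1 was also counted outside FAP-like cells and macrophages, in the critical and subcritical library. It was at 524 and 566 CPM in tenocyte-like, 568 and 114 in myogenic-like and 101 and 5.02 in mural-like cells. Lyz2 was at 355 and 174, 152 and 181, and 519 and 181 CPM in the same classes. In critical macrophage-like cells, Spp1 was at 4241.5 CPM with Lyz2 at 21043.8. Macrophage RNA may therefore bring the mural-like Spp1, which cannot be taken as those cells' own. What Lyz2 would bring was not worked out for these classes.

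On FAP-like cells the CD34 antibody gave 1.16, 0.296 and 0.392 counts per cell in the critical, subcritical and uninjured library, and 0.385 in the critical once aggregates were left out. Gr-1, an antigen of neutrophils and monocytes, gave 1.58 counts per subcritical FAP-like cell and 0.70 without aggregates.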
